A study of Mus musculus with 4 samples.

How the data were processed

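The deposited files were a matrix of Tn5 insertion counts in 295628 peaks of 501 bp by 39220 cells, a list of cell barcodes with library names, a table of metadata per cell and a table of the peaks. Per the submitters' processing notes, reads were aligned to GRCm38/mm10 and processed with ArchR, whose version is not given. Peak calling, cell filtering, clustering, doublet scoring, gene assignment and cell annotation were the authors' and were taken as deposited. The matrix values are whole-number counts per peak and cell from 1 to 4, not normalised by the authors, and no entry was above 4. Entries of 1, 2, 3 and 4 made up 36.0%, 58.3%, 2.58% and 3.07% of the nonzero entries, so higher counts appear to have been capped. Entries at 4 were 2.00% and 2.60% of those of the control libraries and 3.33% and 4.36% of those of the knockdown libraries. Cell totals of the matrix correlated at 0.99988 with the deposited reads in peaks, with a ratio of 0.999, which fixed the order of cells.

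The deposited metadata per cell, named per the file headers, gave fragments, reads in peaks and RNA molecules (UMIs) as counts, transcription start site enrichment and doublet enrichment as ratios computed by the authors, and reads in peaks over all reads as a fraction. The GC content of each peak was deposited as a fraction. Fragments, enrichment and fraction in peaks were used to describe the libraries, and the doublet enrichment and the fragments were used to select cells in alternatives. RNA molecules per cell were used as a measure of depth alone, since no RNA matrix was analysed. Positions are on GRCm38; gene coordinates came from a RefSeq table of the same build, in which 27140 of 38390 deposited gene symbols were found. The annotations of the authors numbered 15 and their clusters 14, and the data the clustering used are not stated.

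The unit of every test was the library, with n = 2 a group, except in the tests of peak types, where it was the peak. Counts were summed per library over the cells of a class. The fibroblast class held the annotations with Fibroblasts in their name and Myofib-like cells. The epithelial class held AT2, Cycling AT2 and Transitional epithelial cells. This assignment of annotations to classes was made after the annotations had been seen, whereas the comparisons, tests, thresholds, gene lists and most alternatives were fixed before the data were examined. EMT-like, SMC, Unknown Mesenchymal and mesothelial cells were left out of both classes, and EMT-like and Unknown Mesenchymal cells were tested on their own. A gene's value was the sum over the peaks whose deposited nearest gene it was.

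Peaks and genes were tested with edgeR 4.0.16, using TMM factors, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and F tests of knockdown against control. P-values were adjusted by Benjamini-Hochberg over all tested features, and 0.05 was the threshold; for each list they were also adjusted over the list alone. The difference of the knockdown effect between the classes was tested in 1 fit of both classes, with the library as a block and the class-by-group term. Values are printed as log2 fold change with the standard error from the fit, and levels as TMM-CPM with the SD over 2 libraries. Shares of cell types were compared by an exact two-sided permutation test, and intervals on single shares are exact binomial at 95%. Peak types were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg over the tests.

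Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, for which only 2 residual degrees of freedom were available. In fibroblasts the 12 fixed lists were YAP/TAZ targets, AP-1 and TEAD factors, Wnt ligands and R-spondins, Wnt response, contractile and cytoskeletal genes, extracellular matrix, alveolar and lipofibroblast genes, TGF-beta and BMP signalling, inflammatory fibroblast genes, growth factor ligands, Notch signalling and cell cycle. In epithelium 16 lists were fixed: these 12 and AT2, AT1, transitional and airway markers. The remaining marker lists of fibroblasts, epithelium, endothelium, immune cells, smooth muscle and pericytes and mesothelium, and in fibroblasts also the 4 epithelial ones, were adjusted as a separate family. Genes were named by rule: 12 genes always (Yap1, Wwtr1, Tead1 to Tead4, Ctgf, Cyr61, Ankrd1, Amotl2, Lats2 and Wnt4), the 10 genes and 5 peaks with the smallest p in each direction, and up to 3 members of each list with the smallest p. The genes and peaks with the smallest p were taken among those in which both libraries of a group lay beyond both of the other, without predicted gene models named Gm or Rik. Of the genes so chosen 2 are not reported here; they stayed in all tests and lists.

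Peaks open in fibroblasts and closed in epithelium were the 7189 with a mean of at least 2 CPM in the fibroblast class and at least 8 times the mean of epithelial cells outside cluster C1, and peaks open in epithelium were defined the other way round. Their level in the epithelial sums was expressed as a percentage of the level in the fibroblast sums of the same library. Sensitivity of the tests was checked on simulated counts with 200 changed features at 1.5-fold and 2-fold. All features had 1 common spread, and the adjustment is stricter where few features differ. The shares recovered are therefore not the sensitivity in the data. At the estimated spread, edgeR recovered 44% and 92% in fibroblast peaks, 93% and 99% in fibroblast genes, 0% and 1% in epithelial peaks and 48% and 91% in epithelial genes, and 3% of 2-fold differences between classes. False calls were 4.90%, 3.03%, 0%, 2.11% and 0% of all calls, and the 0% values rest on few calls. With a lower simulated spread they were, in the same order, 4.03%, 4.5%, 1.24%, 8.42% and 7.61%. The values for epithelial genes and for the difference between classes then lay above the threshold.

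Alternatives were median-of-ratios and total-count scaling, no filter and a filter of a mean of 50 counts, DESeq2 1.42.0, the replicate number as a block, offsets for GC content (lowess, span 0.3) with and without that block, each library left out, cells without the 10% highest doublet scores, equal numbers of cells per library, cells counted as open or closed, promoter peaks alone, and the 1000 peaks with the smallest p. Added after the files had been seen were cells matched on fragments per cell in bins of 8 per doubling, all mesenchymal annotations, single annotations with at least 50 cells per library, cells outside cluster C1, crossed replicate numbers, the gene-level difference between classes and epithelial cells with under 0.5% of counts in fibroblast-open peaks. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Motif enrichment was not run because no genome sequence was used, and no comparison with other series was made.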

Results

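Alveolospheres are co-cultures in which alveolar type 2 (AT2) cells, the surfactant-producing epithelial cells of the lung, grow together with lung fibroblasts. Here they were made from mouse AT2 cells sorted with a lysosome dye and from fibroblasts sorted for PDGFRα, the receptor that marks alveolar fibroblasts. Chromatin accessibility was measured per cell by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, on a platform that also reads RNA from the same nuclei. The groups were 2 control cultures and 2 cultures in which YAP and TAZ, transcriptional co-activators of the Hippo pathway that bind TEAD factors, were knocked down in the fibroblasts. All 4 cultures received 3 µg/mL doxycycline from day 7 to collection on day 14. The comparisons ask which cell states, and which regions of open chromatin in fibroblasts and in their epithelial neighbours, differ after the knockdown, and the study's title gives Wnt4 as a gene of interest.

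The control libraries held 12803 and 11741 cells and the knockdown libraries 8808 and 5868 cells. Insertions counted in peaks were nearly equal per library, between 133882138 and 143334262, so knockdown cells were deeper. The median number of fragments per cell was 8985 and 10436 in the controls and 14466.5 and 23510.5 in the knockdown libraries. Sums over fibroblast cells held 83241853 to 97960320 insertions per library, and sums over epithelial cells 18990026 to 26162717. The labels call the libraries biological replicates without saying what is shared between them, so p-values here measure only the spread between these 4 libraries, which may be partly technical.

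Fibroblast states differed most in size between the groups. Cells the authors annotated as Wnt4+ Fibroblasts made up 0.155% ± 0.142 of control cells and 14.4% ± 1.03 of knockdown cells (SD, n = 2 libraries a group). These were 7 of 12803 and 30 of 11741 control cells against 1200 of 8808 and 885 of 5868 knockdown cells. Tgfbi+ Fibroblasts, named for a secreted matrix protein induced by TGF-beta, made up 0.169% ± 0.183 and 8.07% ± 2.33. Cells called Unknown Mesenchymal made up 0.726% ± 0.154 and 5.13% ± 0.894. In the other direction, the cells annotated SMC made up 5.51% ± 0.533 of control and 0.273% ± 0.289 of knockdown cells.

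Inflammatory Fibroblasts-1 made up 8.62% ± 1.01 of control and 2.83% ± 0.656 of knockdown cells, and Inflammatory Fibroblasts-2 7.42% ± 0.552 and 1.77% ± 0.0754. Cycling Fibroblasts made up 7.55% ± 0.254 and 2.56% ± 0.591 and Myofib-like cells 10.2% ± 0.100 and 6.99% ± 1.08. The cells annotated simply Fibroblasts made up 31.1% ± 2.15 and 24.8% ± 0.735. Among epithelial cells, Cycling AT2 cells made up 1.13% ± 0.161 and 2.80% ± 0.605 of all cells. Transitional epithelial cells, the state between AT2 and AT1 cells, made up 4.67% ± 1.32 and 7.77% ± 1.91. The epithelial class as a whole made up 14.8% ± 2.50 and 20.6% ± 2.19, with AT2 cells at 9.03% ± 1.02 and 10.1% ± 3.49. Within that class Transitional cells made up 33.8% and 28.6% in the controls and 28.9% and 47.7% in the knockdown, and AT2 cells 61.2% ± 3.45 and 48.2% ± 11.8. EMT-like cells lay at 12.2% ± 2.44 and 11.2% ± 0.324, Myo1f+ Fibroblasts at 1.28% ± 0.100 and 1.22% ± 0.209 and Wt1+/Wnt4+ Mesothelial cells at 0.317% ± 0.0382 and 0.185% ± 0.00410. An exact two-sided permutation test of 2 against 2 libraries cannot give a p under 0.333, so no share was called different. The names come from the authors' annotation of these cells, so the size of a state is not independent evidence on the gene in its name.

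**Figure D1:**
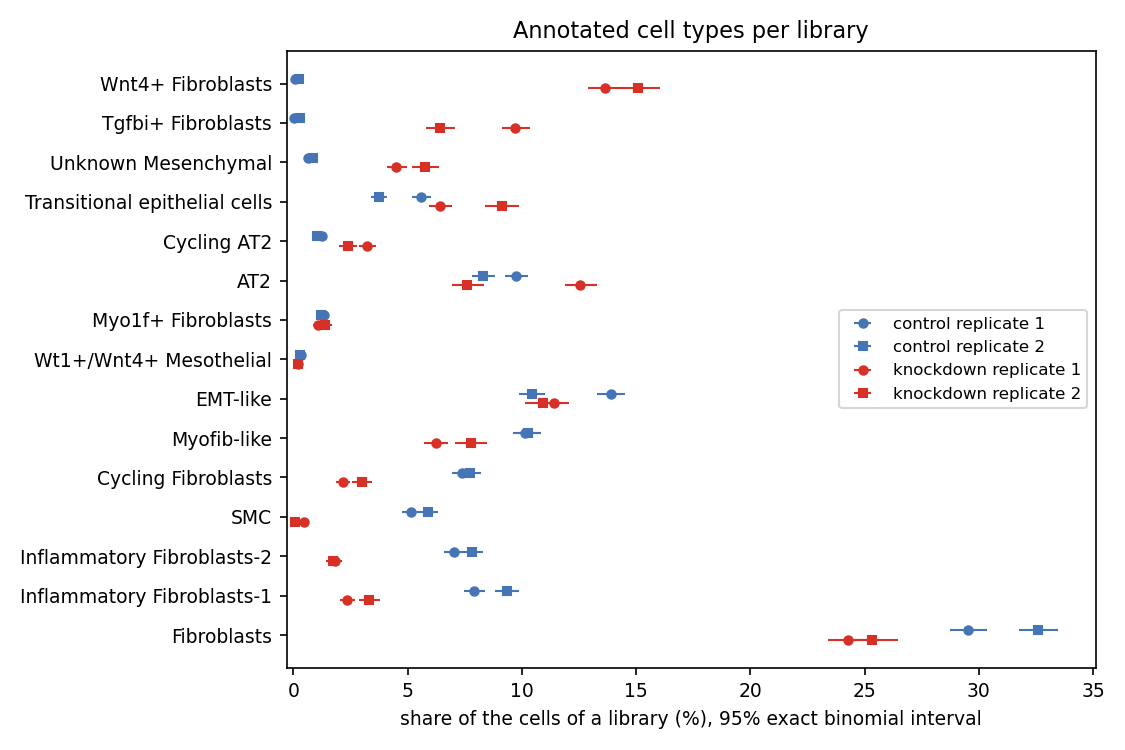
Share of each annotated cell type in each of the 4 libraries, in percent of the library's cells (horizontal axis), with 95% exact binomial intervals that cover counting error only. Wnt4+ and Tgfbi+ Fibroblasts lie between 0.0391% and 0.298% in the control libraries and between 6.42% and 15.1% in the knockdown libraries, and SMC and both inflammatory fibroblast types lie higher in the controls.

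In fibroblasts, accessibility around several genes of the YAP/TAZ pathway was lower after the knockdown. Amotl2, an angiomotin-family gene that YAP and TAZ activate, fell from 83.5 ± 1.14 to 68.4 ± 1.87 CPM, the normalised counts scaled to library size (mean ± SD, n = 2). That was a log2 fold of -0.29 ± 0.03 (SE; edgeR adjusted p = 3.7e-10). The TEAD genes, which code for the DNA-binding partners of YAP and TAZ, fell at Tead2 (log2 fold -0.27 ± 0.06), Tead3 (-0.21 ± 0.03) and Tead4 (-0.19 ± 0.05), with edgeR adjusted p = 6.3e-04, 3.0e-07 and 0.0067. Tead1 stood at -0.03 ± 0.05. Ankrd1, a widely used YAP target, fell by 0.16 ± 0.03 on the log2 scale (edgeR adjusted p = 5.5e-05) and Wwtr1, the gene of TAZ itself, by 0.09 ± 0.04 (edgeR adjusted p = 0.041). Yap1 stood at 0.00 ± 0.04, and the YAP targets Ctgf (-0.10 ± 0.05), Cyr61 (-0.02 ± 0.03) and Lats2 (-0.05 ± 0.04) did not pass the test.

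Single peaks passed at some of these genes. At Amotl2, which lies on chromosome 9 from 102717091 to 102733418 (GRCm38), 9 of 21 peaks fell and 0 rose, among them an intronic peak at 102723160 to 102723660 (log2 fold -0.85 ± 0.19). At Ankrd1 (chromosome 19, 36111965 to 36119844), 10 of 30 peaks fell, including a promoter peak at 36120368 to 36120868 (-0.56 ± 0.16), and 1 distal peak rose. That distal peak, at 36133503, stood at -0.54 in cells annotated Fibroblasts alone and did not pass there. At Tead3 4 of 12 peaks fell, at Tead2 2 of 2, and at Tead4 and Wwtr1 0 of 5 and 0 of 15 passed edgeR. At Cyr61 3 peaks rose and 1 fell among 21. Summed over promoter peaks alone, Ankrd1 passed (-0.26, edgeR adjusted p = 0.012). Amotl2 (-0.01), Tead2 (-0.21), Tead3 (-0.02), Tead4 (-0.12) and Wwtr1 (-0.06) did not (edgeR adjusted p = 0.966, 0.0907, 0.868, 0.577 and 0.628). Accessibility does not measure transcripts, so the values at Yap1 and Wwtr1 do not check the knockdown. With offsets for GC content Wwtr1 no longer passed (-0.05, edgeR adjusted p = 0.29), and in cells matched for depth Tead4 stood at 0.06 (edgeR adjusted p = 0.82). Tead2 (-0.27, edgeR adjusted p = 0.16) and Wwtr1 (-0.13, edgeR adjusted p = 0.20) did not pass in depth-matched cells either, while Amotl2, Tead3 and Ankrd1 did. In cells annotated Fibroblasts alone Amotl2, Tead3 and Ankrd1 still passed and Tead2 did not (-0.23, edgeR adjusted p = 0.089), while Ctgf passed there (-0.21, edgeR adjusted p = 0.046).

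**Figure D2:**
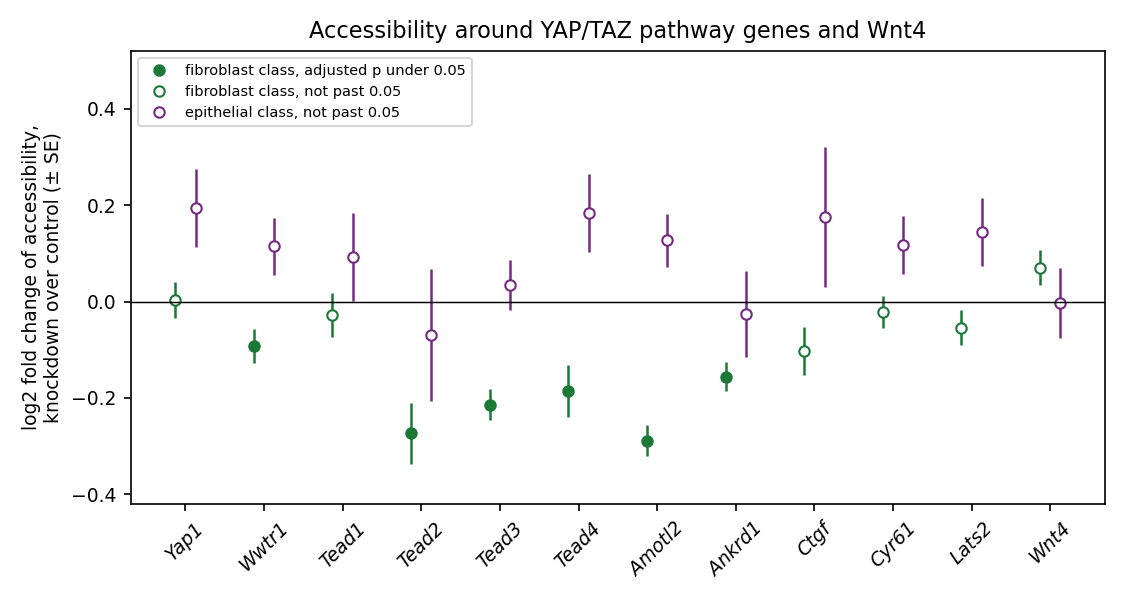
Log2 fold change of accessibility, knockdown over control, with its SE (vertical axis) for YAP/TAZ pathway genes and Wnt4 in fibroblast and epithelial cells, from the sums over 2 libraries a group. Filled points passed an adjusted p of 0.05 in fibroblasts: Amotl2 lies lowest at -0.29 and Yap1 at 0.00, and 0 of the epithelial values passed.

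Wnt4, a secreted Wnt ligand, was more accessible at its promoter in the fibroblast sums of the knockdown. The promoter peak on chromosome 4 from 137276942 to 137277442 rose by a log2 fold of 0.43 ± 0.08 (edgeR adjusted p = 9.7e-06) and the neighbouring promoter peak from 137276287 to 137276787 by 0.55 ± 0.16 (edgeR adjusted p = 0.0054). Both promoter peaks together gave 0.49 ± 0.07 (edgeR adjusted p = 2.1e-09). An intronic peak from 137294936 to 137295436 fell (-0.48 ± 0.16, edgeR adjusted p = 0.025), and the sum over all 19 peaks nearest to Wnt4 did not pass (0.07 ± 0.04, edgeR adjusted p = 0.15). With GC offsets that sum passed at 0.12 (edgeR adjusted p = 0.0073). It did not pass in depth-matched cells (0.03, edgeR adjusted p = 0.85) or in cells annotated Fibroblasts alone (0.08, edgeR adjusted p = 0.30). The Wnt4+ state made up 0.227% of control and 22.9% of knockdown cells of the class. The sums over the class therefore do not separate a change within cells from a change in the mix of states.

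**Figure D3:**
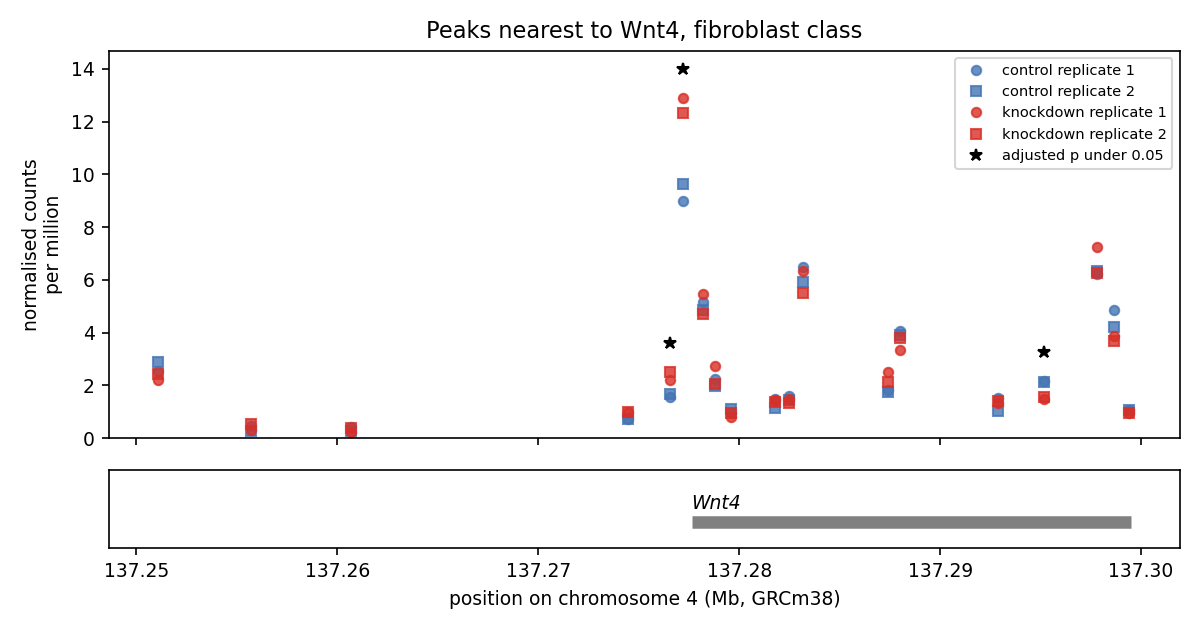
Normalised counts (vertical axis, CPM) of each peak nearest to Wnt4 in fibroblast cells of the 4 libraries, by position on chromosome 4 in GRCm38, above the extent of the gene. Stars mark the 3 peaks past an adjusted p of 0.05: both promoter peaks are higher in both knockdown libraries, and an intronic peak is lower.

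Across the genome, 44807 of 293572 tested peaks differed in fibroblasts (edgeR, Benjamini-Hochberg adjusted p under 0.05), of which 28255 rose and 16552 fell, 2815 and 974 of them by more than 2-fold. The peak that rose with the smallest p was in an intron of Car4, a carbonic anhydrase gene (chromosome 11, 85003441 to 85003941). It went from 2.49 ± 0.362 to 10.3 ± 0.452 CPM (log2 fold 2.04 ± 0.10, edgeR adjusted p = 7.7e-84). The next were near AC129975.2 (4.11 ± 0.22), in an intron of the vitamin C transporter gene Slc23a2 (2.03 ± 0.11), and distal to Lrig3 (2.51 ± 0.14) and the protease gene Prss23 (3.36 ± 0.22). Those that fell with the smallest p were intronic peaks of the sialyltransferase gene St3gal1 (chromosome 15, 67110551 to 67111051; log2 fold -1.45 ± 0.13) and Bpnt1 (-1.64 ± 0.16). They were followed by intronic peaks of the angiopoietin gene Angpt4 (-0.88 ± 0.09) and AC159813.1 (-0.85 ± 0.09), and a distal peak next to Mir96 (-1.09 ± 0.12). These peaks were chosen among those in which both knockdown libraries lay beyond both control libraries. DESeq2 called 15143 peaks, cells matched for fragments per cell 6169, and cells annotated Fibroblasts alone 8167. Without control replicate 1 the count was 25670 and without control replicate 2 24176. The class was held by different clusters in the groups, with cluster C5 at 3.96% ± 1.04 of control and 23.9% ± 8.03 of knockdown cells and cluster C4 at 22.2% ± 0.682 and 6.71% ± 2.30.

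Summed per nearest gene, 11349 of 38212 genes differed in fibroblasts (edgeR, Benjamini-Hochberg), 6574 higher and 4775 lower. The genes that rose with the smallest p included Slc23a2 (24.1 ± 0.0735 to 39.9 ± 0.0509 CPM; log2 fold 0.73 ± 0.04), Fam189a1 (0.96 ± 0.06) and Dcc, the gene of a netrin receptor (0.88 ± 0.06). They also held the carbonic anhydrase-related gene Car10 (0.62 ± 0.05), the complement gene C8b (0.59 ± 0.04), and the adjacent adhesion receptor genes Adgrg3 (0.63 ± 0.04) and Adgrg1 (0.56 ± 0.04). The gene models AC115910.1 (0.99 ± 0.05), n-R5-8s1 (0.60 ± 0.04) and AC115744.1 (0.83 ± 0.06) completed the first 10. The genes that fell with the smallest p included the CCN-family gene Wisp2 (77.0 ± 0.901 to 57.9 ± 2.38; -0.41 ± 0.03), the cytokine gene Il11 (-0.51 ± 0.04), Ptpn14, which codes for a phosphatase that binds YAP (-0.35 ± 0.03), and Pdlim2 (-0.46 ± 0.04). Among them were the matrix genes Hspg2, which codes for perlecan (-0.25 ± 0.03), and Thbs2 (-0.23 ± 0.02). The others were the metalloproteinase gene Mmp23 (-0.44 ± 0.05), Scarf2 (-0.29 ± 0.03), Mir7237 (-0.23 ± 0.02) and Mir96 (-0.99 ± 0.11). DESeq2 called 6825 genes, cells annotated Fibroblasts alone 4660, depth-matched cells 3462 and promoter peaks alone 2127. Without control replicate 1 or 2 the counts were 6712 and 6984. In promoter peaks alone Scarf2 stood at 0.069 and did not pass.

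Of the 12 gene lists fixed before the data were examined, 6 were lower as sets in fibroblasts by camera with a preset correlation. Among 28 measured YAP/TAZ targets 11 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 2.7e-04; adjusted p = 0.196 with an estimated correlation). Ptpn14, Amotl2 and Ajuba, a LIM-domain gene that restrains LATS kinases (-0.27 ± 0.04), had the smallest p. Among 16 AP-1 and TEAD factors 11 fell and 0 rose, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.196 with an estimated correlation). They included Tead3, Vgll3, a TEAD cofactor (-0.16 ± 0.03), and the AP-1 gene Fosl1 (-0.19 ± 0.04). Among 26 extracellular matrix genes 11 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.196 with an estimated correlation). Col1a1, a chain of fibrillar collagen, fell from 140 ± 0.829 to 118 ± 3.50 CPM (-0.24 ± 0.03), the basement membrane collagen Col4a1 by 0.25 ± 0.03 and Sparc by 0.20 ± 0.03 on the log2 scale.

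Among 19 contractile and cytoskeletal genes 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.271 with an estimated correlation). Lmod1 (-0.68 ± 0.09), Tagln (-0.24 ± 0.05) and Cnn2 (-0.23 ± 0.05), which code for actin-binding proteins, were among them. Among 19 cell cycle genes 5 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.271 with an estimated correlation). These included the mitotic genes Cdc20 (-0.20 ± 0.04) and Aurkb (-0.14 ± 0.03) and the replication clamp Pcna (-0.16 ± 0.04). Among 23 TGF-beta and BMP genes 9 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.271 with an estimated correlation). The ligand gene Bmp5 (0.31 ± 0.05) rose and the receptor gene Tgfbr1 (-0.12 ± 0.02) fell. With GC offsets the cell cycle, contractile and TGF-beta lists no longer passed (camera adjusted p = 0.166, 0.147 and 0.527), and in depth-matched cells the cell cycle and contractile lists did not (camera adjusted p = 0.135 and 0.199). With promoter peaks alone the YAP/TAZ target, cell cycle and TGF-beta lists did not pass (camera adjusted p = 0.336, 0.336 and 0.538). In cells annotated Fibroblasts alone the YAP/TAZ target, AP-1 and TEAD, and matrix lists passed (camera adjusted p = 9.1e-04, 2.7e-05 and 0.0045). The contractile, cell cycle and TGF-beta lists passed there too (camera adjusted p = 9.1e-04, 0.0028 and 0.0026). These values used the preset correlation, and an estimated one was not used on these cells.

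The other 6 lists did not pass as sets in the fibroblast sums, although single members did. Over all genes 11349 of 38212 passed edgeR in fibroblasts, and the member counts were not tested against that share. Among 21 Wnt response genes 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.963). The Wnt antagonist gene Dkk2 rose by 0.36 ± 0.04, and the growth genes Ccnd1 (-0.21 ± 0.03) and Myc (-0.20 ± 0.03) fell. Among 23 Wnt ligand and R-spondin genes 3 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.834). Rspo2 stood at 0.20 ± 0.03, Wnt5b at 0.23 ± 0.06 and Wnt10b at -0.13 ± 0.04. Among 19 alveolar and lipofibroblast genes 6 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.131). Bmp5 and the endothelin receptor gene Ednrb (0.24 ± 0.04) rose and Pdgfra (-0.23 ± 0.05) fell. Among 19 inflammatory fibroblast genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.058). The chemokine genes Cxcl1 (-0.21 ± 0.03) and Ccl2 (-0.23 ± 0.04) fell and Cxcl14 (0.22 ± 0.04) rose. This list passed in depth-matched cells and with GC offsets (camera adjusted p = 0.0234 and 0.0218), and the Wnt ligand list passed as higher with promoter peaks alone (camera adjusted p = 0.0465). Over all fibroblast cells and peaks the adjusted p with an estimated correlation was 0.271 and 0.849 for these 2 lists. Among 20 growth factor ligand genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.846). The neuregulin gene Nrg1 (0.33 ± 0.06) and Kitl (0.17 ± 0.04) rose and Hbegf (-0.25 ± 0.04) fell. Among 15 Notch pathway genes 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.068). The ligand gene Jag2 (0.42 ± 0.08) rose, and Lfng (-0.20 ± 0.04) and Rbpj (-0.18 ± 0.04) fell. In cells annotated Fibroblasts alone, where inflammatory states are left out, Ccl2 stood at 0.0030, Cxcl1 at 0.039, Cxcl14 at -0.024, Rbpj at 0.0030 and Wnt10b at 0.0076 on the log2 scale, and 0 of the 5 passed. Fosl1 (-0.035), Bmp5 (0.12), Pdgfra (-0.12), Hbegf (-0.079), Wnt5b (0.16), Tagln (-0.16), Lfng (-0.15), Tgfbr1 (-0.0855) and Kitl (0.12) did not pass in them either. Nrg1 stood at 0.080 in depth-matched cells without passing.

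Peaks that rose in fibroblasts lay away from promoters. Promoters, as the deposited peak table assigns them, were 5.13% of the 28255 higher peaks and 11.9% of the other tested peaks (odds ratio 0.398, 95% interval 0.377 to 0.421). They were 9.32% of the 16552 lower peaks against 11.4% (odds ratio 0.799, 0.757 to 0.843; Fisher's exact test, two-sided, adjusted p = 7.9e-17). Distal peaks were 40.4% of the higher peaks and 32.4% of the others (odds ratio 1.42, 1.38 to 1.45; adjusted p = 2.3e-158), and 35.6% against 33.0% for the lower peaks (odds ratio 1.12; adjusted p = 7.3e-12). Exonic peaks were 4.25% against 5.80% among higher peaks (odds ratio 0.720), but among the 1000 higher peaks with the smallest p this did not pass (odds ratio 0.749, 0.538 to 1.02; Fisher's exact test, adjusted p = 0.102). Peaks are not independent replicates, so these values describe the peak set. With GC offsets edgeR called 24016 higher and 17160 lower peaks. Peak types were compared neither with those offsets nor in depth-matched cells. Entries at 4, the highest value, were more frequent in the knockdown libraries, and their part in the promoter shares was not tested. The test of TEAD, AP-1 and other binding motifs was not run, since no genome sequence was used here.

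In epithelial cells, which were not the knocked-down cells, 2880 of 37676 genes tested differed between the cultures (edgeR, Benjamini-Hochberg), 1329 higher and 1551 lower. Hes1, a Notch target, rose from 268 ± 2.52 to 335 ± 4.38 CPM (log2 fold 0.32 ± 0.04, n = 2), Emp2, an AT1 marker, by 0.40 ± 0.05 and the chloride channel gene Ano1 by 0.52 ± 0.07. The others with the smallest p were Pip5k1b (0.48 ± 0.06), Platr19 (0.52 ± 0.06), Rasgef1a (0.54 ± 0.07), AC122542.1 (0.45 ± 0.06), Bend7 (0.58 ± 0.08), Slain1 (0.53 ± 0.07) and Mir8110 (0.52 ± 0.07). The genes that fell with the smallest p included mesenchymal ones. Pdgfrb, the gene of a receptor of pericytes and fibroblasts, went from 47.6 ± 2.63 to 28.1 ± 2.43 CPM (-0.76 ± 0.09). With it fell the collagen gene Col5a1 (-0.70 ± 0.08), the collagen crosslinking enzyme gene Loxl1 (-0.70 ± 0.08), the mesenchymal growth factor gene Fgf7 (-0.71 ± 0.09) and the CCN-family gene Wisp1 (-0.69 ± 0.07). Fscn1 (-0.45 ± 0.06), Kcnj16 (-0.92 ± 0.12), the chemokine receptor gene Ccr7 (-0.57 ± 0.08) and Crispld2 (-0.68 ± 0.09) also fell. All of these genes had an edgeR adjusted p = 0.0079. DESeq2 called 3535 genes, but edgeR called 0 without control replicate 1 or 2 (5933 and 3902 at an unadjusted p under 0.05), 9765 without knockdown replicate 1 and 4793 without knockdown replicate 2. With the replicate number as a block edgeR also called 0 (7793 at an unadjusted p under 0.05), and 0 with GC offsets added (7343). With total counts as the scaling 34.0% of the calls were higher, against 46.1% in the main scaling.

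The epithelial sums carried signal at peaks that are open in fibroblasts and closed in epithelium. At 7189 such peaks the control sums reached 27.8% and 33.2% of the fibroblast level, and the knockdown sums 16.0% and 4.45%. The 6876 of them that could be tested had a median log2 fold of -1.31 in the epithelial sums, with 98.6% lower, and the 17107 peaks open in epithelium alone had a median of 0.50. Cluster C1, whose cells had a median doublet enrichment of 1.98 against 0.225 in epithelial cells outside it, held 18.1% ± 3.36 of the control and 3.00% ± 3.86 of the knockdown epithelial cells. Without it the control sums still reached 12.3% and 16.8% and the knockdown sums 9.66% and 4.28%, and 163 genes passed edgeR (26 higher and 137 lower). Restricted to epithelial cells with under 0.5% of their counts in fibroblast-open peaks, 0 of 35893 genes passed edgeR, with 1559 at an unadjusted p under 0.05, and DESeq2 was not run on these cells. There Pdgfrb stood at -0.20, Col5a1 at -0.096, Wisp1 at -0.28, Hes1 at 0.16 and Emp2 at 0.094, while Kcnj16 (0.068), Vgll3 (0.020), Krt19 (-0.025), Ptpn14 (-0.0078), Wnt7a (-0.040), Rspo3 (0.22) and Ccl7 (0.28) had the opposite sign. That restriction removes the fibroblast-open signal by construction and kept 72.4% and 74.6% of control and 88.5% and 98.4% of knockdown epithelial cells.

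**Figure D4:**
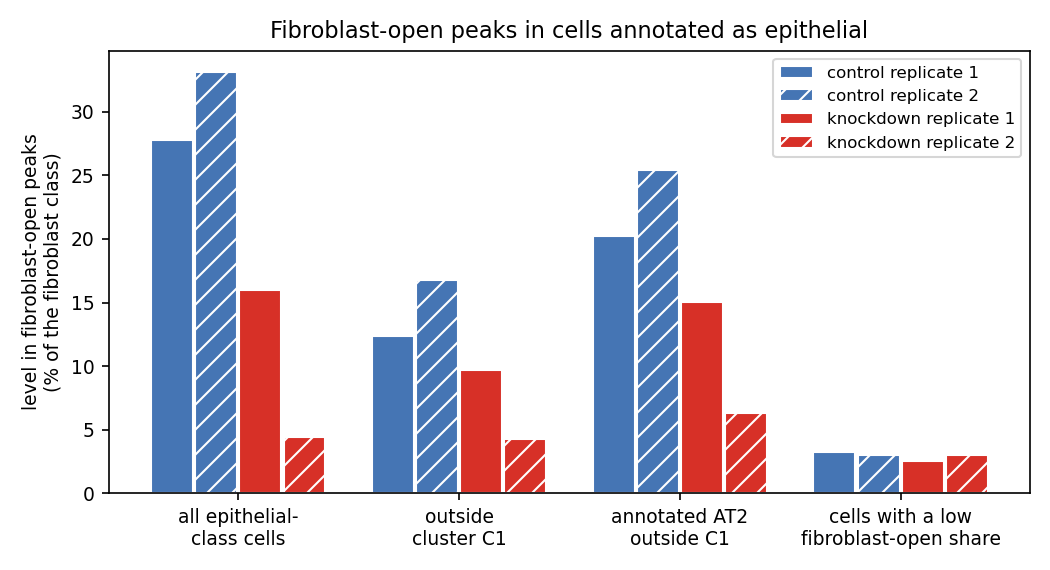
Level of the epithelial sums at peaks open in fibroblasts and closed in epithelium, in percent of the fibroblast level of the same library (vertical axis), for the 4 libraries and 4 selections of epithelial cells. Control libraries lie at 27.8% and 33.2% and knockdown libraries at 16.0% and 4.45% over all epithelial cells, and all 4 lie between 2.53% and 3.21% in cells selected for a low share.

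Of the 16 lists tested in epithelial cells, 5 passed camera with a preset correlation. Among 13 AT2 markers 9 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 9.2e-08; adjusted p = 0.393 with an estimated correlation). They included the surfactant gene Sftpb (0.25 ± 0.05), Lpcat1, which makes surfactant lipid (0.33 ± 0.05), and Cxcl15 (0.71 ± 0.12). Among 14 AT1 markers 8 rose and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.558 with an estimated correlation). Among those that rose were Emp2, Akap5 (0.51 ± 0.08) and the water channel gene Aqp5 (0.40 ± 0.06). Among 13 transitional markers 5 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 1.1e-05; adjusted p = 0.558 with an estimated correlation). Ndnf (0.33 ± 0.06), the keratin gene Krt19 (0.28 ± 0.06) and Hbegf (0.24 ± 0.06) rose. Among 26 extracellular matrix genes 10 fell and 0 rose, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.5e-07; adjusted p = 0.393 with an estimated correlation), including Fbn1 (-0.73 ± 0.11). Among 19 alveolar and lipofibroblast genes 3 fell and 1 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.558 with an estimated correlation). Mfap4 (-0.62 ± 0.13) fell and Npnt (0.36 ± 0.07) rose. With promoter peaks alone the AT1 and alveolar lists did not pass (camera adjusted p = 0.184 and 0.109), and in depth-matched cells the alveolar list did not (camera adjusted p = 0.0561). Without cluster C1 cells 0 AT2, 0 AT1 and 0 transitional markers and 2 matrix genes passed edgeR over all genes. The list medians there were 0.19 for AT2, 0.16 for AT1, 0.09 for transitional and -0.16 for matrix genes, against 0.35, 0.24, 0.20 and -0.24 with all cells. These 4 lists still passed camera there (adjusted p = 6.1e-07, 7.3e-04, 0.0048 and 5.5e-06), and the alveolar list did not (camera adjusted p = 0.0568). In cells with a low fibroblast-open share only the AT2 list passed (median 0.09, camera adjusted p = 0.0088), and the median of the matrix list was -0.0042 (camera adjusted p = 0.555). The 17107 peaks open in epithelium rose as a whole, with a median of 0.50 with all cells. That median was 0.25 without cluster C1 cells and 0.072 in low-share cells. The marker lists were not tested against this general rise, so passing camera does not set them apart from it.

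The other 11 lists did not pass in the sums over all epithelial cells. Over all genes 2880 of 37676 passed edgeR there, and the member counts were not tested against that share. Among 28 YAP/TAZ targets 2 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.293). Wwc1, a Hippo scaffold gene, stood at 0.43 ± 0.07, Ptpn14 at 0.19 ± 0.05 and Fjx1 at -0.44 ± 0.09. Among 23 Wnt ligand and R-spondin genes 1 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.279). Wnt7a stood at 0.29 ± 0.06, Wnt16 at -0.56 ± 0.13 and Rspo3 at -1.38 ± 0.28. Among 21 Wnt response genes 2 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.293). Sp5 stood at 0.31 ± 0.08, Dkk3 at -0.45 ± 0.06 and Sfrp1 at -0.69 ± 0.10. Among 15 Notch genes 2 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.232). Hes1 and Jag2 (0.52 ± 0.11) rose and Heyl (-0.42 ± 0.10) fell. Among 20 growth factor ligand genes 3 rose and 2 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.647), among them Fgf1 at 0.21 ± 0.05. Among 19 inflammatory genes 0 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.141). The chemokine genes Ccl2 (-1.28 ± 0.26), Ccl7 (-1.14 ± 0.27) and Cxcl14 (-0.55 ± 0.13) were among them. The list passed in depth-matched cells and with promoter peaks alone (camera adjusted p = 0.0138 and 0.00398; adjusted p = 0.616 with an estimated correlation over all cells), but not in low-share cells (camera adjusted p = 0.987). Among 16 AP-1 and TEAD factors 1 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.647), Vgll4 (0.19 ± 0.05) and Vgll3 (-0.62 ± 0.09). In the cell cycle list (19 genes; camera adjusted p = 0.293), the contractile list (19; 0.981), the TGF-beta and BMP list (23; 0.647) and the airway list (7; 0.665) edgeR passed 0 genes, with 0 also adjusted over the list alone. Mcm3 (0.24 ± 0.10), Myh9 (0.17 ± 0.05), Skil (0.18 ± 0.06) and Trp63 (-0.17 ± 0.07) had the smallest p in them. In Transitional cells alone, where edgeR passed 0 genes (2238 at an unadjusted p under 0.05), Wnt16 (0.024), Sfrp1 (0.031), Heyl (0.0046), Vgll4 (-0.012) and Sftpb (-0.096) had the opposite sign. In promoter peaks alone Fjx1 (0.066), Wnt16 (0.22) and Lpcat1 (-0.053) did.

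No single peak passed in epithelial cells. Of 273400 peaks, edgeR called 0 (52621 had an unadjusted p under 0.05) and DESeq2 called 4872. The peaks with the smallest p, which did not pass, were higher at the promoters of Tmem189 (log2 fold 1.07 ± 0.13), Ralgps2 (1.03 ± 0.13) and Larp1b (1.07 ± 0.14) and in introns of Clic5, an AT1 marker (0.98 ± 0.13), and Slc26a9, an anion transporter gene (0.98 ± 0.13). They were lower at AC155808.1 (-2.43 ± 0.33), Mir193b (-1.01 ± 0.14), Vgll3 (-2.94 ± 0.44), Sh3pxd2b (-1.54 ± 0.24) and Liph (-1.65 ± 0.25), all with an edgeR adjusted p = 0.054. Around the 12 genes of the YAP/TAZ pathway and Wnt4 edgeR called 0 epithelial peaks and 0 gene sums. Yap1 stood at 0.19 ± 0.08, Wwtr1 at 0.11 ± 0.06, Amotl2 at 0.13 ± 0.05, Tead4 at 0.18 ± 0.08 and Wnt4 at 0.00 ± 0.07. In promoter peaks alone Amotl2 passed in epithelium (0.43, edgeR adjusted p = 0.012). In data simulated with the spread estimated from the epithelial sums, the test recovered 1% of 2-fold changes in epithelial peaks and 91% in epithelial genes, against 92% in fibroblast peaks. Without knockdown replicate 1 edgeR called 46217 epithelial peaks, and without knockdown replicate 2, control replicate 1 or control replicate 2 12452, 910 and 779.

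The knockdown effect itself differed between the classes at 2379 of 295620 peaks by the interaction test (edgeR, Benjamini-Hochberg, library as a block), 1646 with the higher value in fibroblasts and 733 with the higher value in epithelium. At gene level 3411 of 38393 differed. Amotl2 had a log2 effect 0.40 ± 0.06 lower in fibroblasts than in epithelium (edgeR adjusted p = 0.014). Ptpn14 (-0.53 ± 0.05), Tead3 (-0.23 ± 0.05) and Tead4 (-0.36 ± 0.08) also had lower effects in fibroblasts (edgeR adjusted p = 0.013, 0.033 and 0.036). Wwtr1 (-0.19 ± 0.06), Yap1 (-0.17 ± 0.09), Ankrd1 (-0.11 ± 0.11) and Wnt4 (0.09 ± 0.07) did not pass. Of 51 named genes tested, most of them chosen for a small p within 1 class, 28 passed, and 18 of these also passed without cluster C1 cells. Amotl2 (-0.30) and Ptpn14 (-0.44) were among the 18, but neither Tead3 (-0.19, edgeR adjusted p = 0.086) nor Tead4 (-0.23, edgeR adjusted p = 0.20). The peak count fell to 6 without cluster C1 cells and to 0 without either control replicate or with total counts as the scaling (59917 at an unadjusted p under 0.05; DESeq2 called 443). It was 48874 without knockdown replicate 1 and 11477 without knockdown replicate 2. With median-of-ratios scaling 217 peaks passed, 18.9% of them higher in fibroblasts against 69.2% in the main scaling, and with GC offsets 2142, of which 964 were higher.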

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

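The explanations for the fibroblast peaks and the test of doublets were written down with their bounds before their tests were run; those for the epithelial signal in cluster C1 and for epithelial depth were written after the result was seen. The low-share selection, the comparison over the same peaks and the rule that leaves epithelial depth open were also chosen after the results they bear on were seen.

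The effect of the knockdown differed between fibroblasts and epithelium at 2379 peaks and 3411 genes, and at 28 of the 51 named genes tested. Most of these 51 were chosen for a small p within 1 class, which raises that share. The log2 effect was lower in fibroblasts, where YAP and TAZ were knocked down, at the Hippo pathway genes Amotl2 (-0.4006), Ptpn14 (-0.5321), Tead3 (-0.2331) and Tead4 (-0.3604). It was also lower at Hes1 (-0.414), Emp2 (-0.4161), Ano1 (-0.6691), Slain1 (-0.4075), Pdlim2 (-0.5649), Mmp23 (-0.4091), Mir8110 (-0.4851) and AC122542.1 (-0.3435). It was higher in fibroblasts at mesenchymal genes, namely Pdgfrb (0.5949), Col5a1 (0.5766), Loxl1 (0.5522), Fgf7 (0.7545), Wisp1 (0.5118), Crispld2 (0.5772) and Fscn1 (0.335). It was higher as well at Dcc (1.55), Fam189a1 (1.049), Kcnj16 (0.8616), Ccr7 (0.4662), Adgrg3 (0.4455), Adgrg1 (0.2637), C8b (0.2813), AC115744.1 (0.7014) and n-R5-8s1 (0.704). For the mesenchymal genes the difference came from falls in the epithelial sums, where Kcnj16 (-0.92) and Ccr7 (-0.57) fell as well. At the Hippo pathway genes part of the difference lay in higher epithelial values, at Amotl2 (0.13), Ptpn14 (0.19), Tead3 (0.03) and Tead4 (0.18). In epithelial cells with a low fibroblast-open share these 4 stood at -0.057, -0.0078, -0.042 and -0.053. Without cluster C1 cells 1176 genes and 6 peaks passed, of which 4 peaks were among the 2379 in the same direction, and Hes1 (-0.33), Pdlim2 (-0.48), Dcc (1.31) and Fgf7 (0.50) still passed. Of the 28 genes 10 no longer did, namely Pdgfrb (0.31), Wisp1 (0.30), Fscn1 (0.19), Ccr7 (0.22), Ano1 (-0.41), Slain1 (-0.19), Mir8110 (-0.30), AC122542.1 (-0.20), Tead3 (-0.19) and Tead4 (-0.23). Without that cluster the epithelial sums still held fibroblast-open signal, at 12.35% and 16.79% of the fibroblast level in the controls and 9.66% and 4.28% in the knockdown. Passing there does not separate a class difference from that signal. The difference between classes was not tested in low-share cells.

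The fall of fibroblast-open peaks in the epithelial sums was weighed against 3 explanations. Fibroblast chromatin in cells annotated as epithelial, more in the controls, remained undecided: without cluster C1 cells the median log2 fold was -0.9622 over the 3460 peaks that could still be tested, against -1.37 at the same peaks with all cells, which was neither the halving the explanation called for nor an unchanged value. Summed over all 7189 peaks without a filter, the log2 ratio was -1.06 without cluster C1 cells and -1.58 with them. Depth per cell remained undecided as well. The median was -1.654 in depth-matched cells, but matching took the deeper control cells, whose level rose from a mean of 30.4% to 39.6% of the fibroblast level, so the selection can itself enlarge the fall. Doublets of an AT2 cell with a fibroblast outside cluster C1 met the prediction written for them, with the AT2 cells of the highest fragment quartile carrying 4.568 times the fibroblast-open share of the lowest in control replicate 1 and 5.51 times in control replicate 2. The ratio was also 5.48 and 4.30 in the knockdown libraries, so it shows fibroblast signal in deep AT2 cells of every library and not why the control sums held more of it. Epithelial cells in cluster C1 had a median of 18330 fragments and 7187 RNA molecules, against 9559 and 3758 outside it. In knockdown replicate 2 its 3 cells had fewer fragments (11992 against 20651.5). The cluster held 20.5% and 15.7% of control and 5.73% and 0.268% of knockdown epithelial cells. That order follows both the number of cells per library and the group, which cannot be told apart here. Fibroblast-like chromatin of the epithelial cells' own was not tested, and an effect of the knockdown on epithelial cells remains open.

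A selection of epithelial cells with under 0.5% of counts in fibroblast-open peaks brought those sums to 3.21%, 3.02%, 2.53% and 2.98% of the fibroblast level, and edgeR called 0 genes and 0 peaks in it. It kept 1538 of 2124 and 1143 of 1532 control cells and 1731 of 1955 and 1103 of 1121 knockdown cells. Among all epithelial cells, kept or not, 12, 8, 7 and 1 lay within 20% of the 0.5% cut. The selection lowers the fibroblast signal by construction and leaves fewer control counts (13368148 and 10454943), so 0 calls there do not show that the epithelium did not respond.

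The fibroblast peaks past the threshold were weighed against 3 explanations, and none met the bound written for it as the whole cause. In depth-matched cells the called peaks kept 1.058 times their median fold, in the direction that kept less, although only 12.9% were called again with 1196 cells per library. With GC offsets 82.2% were called again in the same direction. In cells annotated Fibroblasts alone they kept 0.6393 of their fold and 13.8% were called again, with 92.35% of the same sign. A shift between annotated states therefore remains a possible part of the difference. The depth-matched cells and the Fibroblasts alone were part of the cells that gave the called peaks. Some of the kept fold is therefore built in. Matching also took the deeper control cells, with medians of 17824 and 17846.5 fragments against 8981 and 10497 in all control fibroblasts. A part played by depth is therefore not excluded. A response of fibroblast chromatin to the loss of YAP and TAZ remains as a hypothesis, which RNA of the same cells and further cultures would test.

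The same nuclei carried RNA libraries that were not analysed here, with a median of 3598 and 4830 molecules per cell in the knockdown libraries against 2882 and 3151 in the controls. They are the direct way to measure Yap1, Wwtr1 and Wnt4 transcripts.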

How the results depend on the processing

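The alternatives were set before the data were examined except depth matching, the cell subsets by annotation, cluster or fibroblast-open share, crossed replicates, and the gene-level difference between classes, which were chosen after the files or a result had been seen. The cause of the differences below was not tested, and the main results were kept whatever an alternative gave.

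In fibroblasts, where 44807 peaks and 11349 genes passed, DESeq2 called 15143 peaks and 6825 genes. Leaving out 1 library gave 24176 to 35917 peaks (25670 without control replicate 1) and 6712 to 10016 genes (6984 without control replicate 2). Equal cell numbers gave 26136 peaks. Depth-matched cells gave 6169 peaks and 3462 genes, cells annotated Fibroblasts alone 8167 and 4660, and promoter peaks alone 2127 genes. Of 1696 values for named genes 1533 were the same, 144 weaker, 6 stronger and 13 reversed. The log2 fold turned in depth-matched cells for Tead4 (0.055). It turned in Fibroblasts alone for Wnt10b (0.0076), Cxcl1 (0.039), Ccl2 (0.0030), Cxcl14 (-0.024), Rbpj (0.0030), Slc34a2 (0.015), Kdr (0.073), Wt1 (0.059) and the Ankrd1 peak at 36133503 (-0.54), and with promoter peaks for Scarf2 (0.069), Wnt10b (0.088), Cdh1 (0.021) and Elf3 (-0.17); none of the turned values passed.

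In epithelium, where 0 peaks passed, peak calls were 2352 with median-of-ratios scaling, 3748 with no filter, 3476 with a mean of at least 50 counts, 4872 with DESeq2, 4689 with GC offsets, 3805 with equal cells, 4237 with open or closed cells and 57 without the top doublet scores. Leaving out 1 library gave 779 to 46217 (910 without control replicate 1 and 12452 without knockdown replicate 2), AT2 cells alone gave 2452 and Transitional cells alone 2. The count stayed 0 with total counts, in depth-matched cells, outside cluster C1 and in low-share cells.

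The 2880 epithelial genes became 0 without either control replicate, 9765 without knockdown replicate 1 and 4793 without knockdown replicate 2. They became 588 without the top doublet scores, 163 without cluster C1, 1128 in AT2 cells outside it, 1062 with promoter peaks, and 0 in low-share cells and in Transitional cells alone. With total counts 34.0% of the calls were higher, against 46.1% in the main scaling. Of 2038 values for named genes 1516 were the same, 449 weaker, 49 stronger and 24 reversed. In low-share cells the fold turned for Kcnj16 (0.068), Ptpn14 (-0.0078), Wnt7a (-0.040), Rspo3 (0.22), Ccl7 (0.28), Vgll3 (0.020), Esrp1 (-0.014), Krt18 (-0.012) and Krt19 (-0.025), and the transitional marker list had a median of -0.019. In Transitional cells alone it turned for Kcnj16 (0.041), Ptpn14 (-0.057), Wnt7a (-0.18), Wnt16 (0.024), Rspo3 (0.19), Sfrp1 (0.031), Heyl (0.0046), Vgll4 (-0.012), Esrp1 (-0.042), Krt18 (-0.038), Sftpb (-0.096) and Krt19 (-0.042). With promoter peaks it turned for Fjx1 (0.066), Wnt16 (0.22) and Lpcat1 (-0.053). None of these values passed.

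The 2379 peaks with a different effect between the classes became 217 with median-of-ratios scaling, 0 with total counts, 0 with a mean of at least 50 counts, 443 with DESeq2, 8871 with equal cells, 8413 with open or closed cells, 132 in depth-matched cells and 6 without cluster C1. Leaving out 1 library gave 0 to 48874, with 0 without either control replicate and 11477 without knockdown replicate 2.

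With an estimated correlation 0 of the 6 fibroblast lists and 0 of the 5 epithelial lists passed camera, and in low-share cells 1 epithelial list did. Of 90 values for shares of all cells 89 were the same, 1 moved and 0 reversed. A share counted as the same when its difference moved by less than the larger SD of the groups. With 2 libraries a group, leaving out 1 library cannot move it that far. Only the values without the top doublet scores could come out otherwise, so these counts say little about leaving out libraries. AT2 cells stood at 1.12 times their control share of all cells and 0.788 times that of the epithelial class, and Myo1f+ Fibroblasts at 0.949 of all cells and 1.02 of non-epithelial cells. Both AT2 ratios include cluster C1 cells, which were more frequent among control AT2 cells, and were not computed without them.

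The replicate numbers were also used as a block, although nothing in the labels pairs the cultures. Deviations of same-number libraries correlated at -0.000396 for peaks and 0.00403 for genes in fibroblasts and at -0.195 and -0.291 in epithelium. With it epithelial peak calls were 715, or 3929 with GC offsets, epithelial genes 0 and 0, and differing peaks 0 and 74. With the numbers crossed 22354 epithelial peaks and 8178 epithelial genes were called.

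Among the 1000 peaks with the smallest p in each direction, exonic peaks among the higher and intronic peaks among the lower no longer passed (odds ratio 0.749 and 0.957); the other 6 tests of peak type were the same.

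The motif tests were not run for lack of a genome sequence, so neither their 2 thresholds nor their 2 backgrounds were compared.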

Other observations

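The peaks near Cyr61, a YAP target whose sum did not pass in fibroblasts, moved in both directions: distal peaks on chromosome 3 at 145640580 to 145641080 (log2 fold 0.44 ± 0.09), 145618245 to 145618745 (0.46 ± 0.13) and 145641273 to 145641773 (0.35 ± 0.09) rose and the one at 145632817 to 145633317 fell (-0.56 ± 0.14). At Yap1 the promoter peak on chromosome 9 from 8003800 to 8004300 rose (0.26 ± 0.09, edgeR adjusted p = 0.035). Within the fibroblast class the Wnt4+ state made up 0.227% of control and 22.9% of knockdown cells, and cells annotated Fibroblasts made up 46.7% and 39.6%. Tested alone, those Fibroblasts had 8167 peaks past edgeR, Myofib-like cells 681 (342 higher and 339 lower), EMT-like cells 354 (292 higher), Cycling Fibroblasts 4 and Inflammatory Fibroblasts-1 2.

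Markers of other cell types also moved within the fibroblast sums, a set of lists adjusted apart. Their counts stand beside 11349 of 38212 genes that passed edgeR over all genes in fibroblasts, and were not tested against that share. Among 15 fibroblast markers 1 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.668 with an estimated correlation), with Pdgfrb at -0.18 ± 0.03. Among 13 transitional markers 1 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.668 with an estimated correlation), with Tnip3 at 0.36 ± 0.05 and Lgals3 at -0.18 ± 0.03. Among 6 mesothelial markers 0 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.668 with an estimated correlation): Msln (-0.26 ± 0.06), Wt1 (-0.12 ± 0.03) and Upk3b (-0.17 ± 0.06). The mesothelial list did not pass with GC offsets, in depth-matched cells or with promoter peaks alone (camera adjusted p = 0.0524, 0.0721 and 0.216), nor the transitional list with promoter peaks alone (camera adjusted p = 0.122). In cells annotated Fibroblasts alone the fibroblast, transitional and mesothelial lists did not pass (camera adjusted p = 0.329, 0.329 and 0.429), and Wt1 stood at 0.059 there. The other 7 did not pass camera as sets. Counts adjusted over the list alone were 1 higher and 2 lower of 7 airway markers (camera adjusted p = 0.30; Muc5b 0.58 ± 0.14), 3 and 4 of 14 AT1 markers (0.419; Pdpn -0.15 ± 0.03), 2 and 2 of 13 AT2 markers (0.649; Hc 0.26 ± 0.06 and Abca3 -0.22 ± 0.05) and 2 and 1 of 9 endothelial markers (0.419; Emcn 0.40 ± 0.06). They were 1 and 2 of 11 epithelial markers (0.649; Krt18 -0.30 ± 0.06), 0 and 2 of 9 immune markers (0.413; Csf1r -0.21 ± 0.04) and 1 and 0 of 10 smooth muscle and pericyte markers (0.676; Kcnj8 0.13 ± 0.04).

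In the epithelial sums, among 15 fibroblast markers 7 fell and 0 rose, or 11 and 0 adjusted over the list alone (camera adjusted p = 8.5e-10; adjusted p = 0.313 with an estimated correlation), including the mesenchymal transcription factor genes Foxf1 (-0.94 ± 0.17) and Tbx4 (-0.47 ± 0.09). Among 11 epithelial markers 5 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 4.5e-07; adjusted p = 0.313 with an estimated correlation), including Foxa2 (0.41 ± 0.08) and Esrp1 (0.34 ± 0.06). In low-share cells neither list passed (camera adjusted p = 0.078 and 0.537). Among 8 endothelial markers 1 fell, Erg (-0.70 ± 0.11), also adjusted over the list alone (camera adjusted p = 0.119). Among 9 immune, 6 mesothelial and 10 smooth muscle and pericyte markers edgeR passed 0, with 0, 0 and 4 lower adjusted over the list alone (camera adjusted p = 0.615, 0.278 and 0.119); Lyz2 stood at 0.15 ± 0.18, Wt1 at -0.80 ± 0.21 and Des at -0.44 ± 0.12.

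In cells annotated epithelial, the fibroblast-open share of the median AT2 cell outside cluster C1 was alike in the 4 libraries, at 0.123% and 0.116% in the controls and 0.0976% and 0.117% in the knockdown, and the libraries differed in the cells of the highest fragment quartile (1.15%, 1.56%, 1.08% and 0.429%) and of the third (0.676%, 0.612%, 0.263% and 0.197%), and also of the lowest (0.253%, 0.282%, 0.196% and 0.0999%). In the other direction, epithelium-open peaks in the fibroblast sums reached 7.07%, 7.17%, 5.40% and 5.92% of the epithelial level. Among peaks that rose in fibroblasts the median distance to a transcription start site was 19640 bp, and among those that fell 11930 bp.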
